A study of Oncorhynchus mykiss with 7 samples.

How the data were processed

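Total RNA from muscle of 7 rainbow trout (3 fed, 4 restricted) was labelled with Cy3 by an oligo-dT primed one-colour protocol, per the labels, and hybridised to Agilent arrays of design 016320, per the file headers. The scans were read with Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes and the file headers, under the protocol GE1-v5_95_Feb07. The deposited scanner files hold the intensity of each of 45220 spots on a linear scale, of which 43803 were not controls. The processed intensity is the background-subtracted signal of the Feature Extraction program, per the file headers. The deposited series matrix holds log2 values of the same arrays with no stated scale. Setting each of its 7 columns against the scanner values showed that these log2 values follow the log2 processed signal minus the 75th percentile of the array, minus the median of the 3 fed arrays for each probe. Correlations with this recomputation were 0.999 or higher. The gap was under 0.01 for 99.7% to 99.8% of values on 6 arrays and for 21.2% on restricted array 2, where the median gap was 0.0104. The column medians were 0, -0.05 and 0 for fed arrays 1, 3 and 4 and -0.18, -0.22, -0.30 and -0.29 for restricted arrays 1, 2, 3 and 4. Scale, centring and direction were thereby settled, and that table was used only as an alternative. Its 37454 rows matched 37394 probes of the scanner files.

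The log2 processed signal minus the 75th percentile of each array over spots that were not controls was used. Control spots and spots with outlier flags were left out, spots of one probe were averaged, and probes well above background on at least 3 of the 7 arrays were tested. Groups were taken from the sample labels. Restricted minus fed differences were fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 20686 probes and a threshold of 0.05. Means are log2 signals relative to the 75th percentile. Values after ± are standard errors of limma's log2 difference, unless marked SD. The median standard error was 0.292 with 3 and 4 arrays. Where a group was not well above background on any of its arrays, the fold is given as a lower bound. For this, the mean of the brighter group was set against the mean, over arrays of the dimmer group, of the higher of the lowest signal among probes well above background and the probe's own signal.

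Probes were named by the product text in the scanner files, which is mostly a sequence similarity to proteins of other species and can be old. Of 37394 probes, 17056 carried a product name, and 15210 of these were not of the weak similarity class. Positions in a genome were not used here. Trout carry duplicated genes, so a probe can read several copies. The comparison, its test, the lists and the alternatives were chosen before the data were examined, as was the rule for named genes. By that rule the text names the 12 largest rises and the 12 largest falls among named probes past the threshold whose groups did not overlap, 1 probe per name. Of each list it names up to 4 members with the smallest p past the threshold over all probes or over the list, or the member with the smallest p if none passed, and certain genes whatever their result, except for 1 result that is not reported here. Of the certain genes, fbxo32, trim63, igf1, igfbp1 and pdk4 were not matched, and hsp90aa1, fasn and scd were matched but not tested. Values named beyond this rule (apolipoprotein B, alpha-1-microglobulin, alpha globin, transferrin TC128251 and the counts over further probes of a gene) were chosen after they were seen.

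The 30 gene lists held 474 members, of which 314 were matched to probes through spellings of their names. Of 1704 matched probes, 1022 matched a spelling fixed in advance and 682 a spelling added after the product names, but no test, had been read. A further 203 probes that named another gene were dropped. Each member was represented by its brightest tested probe. Lists of 5 or more measured members (25 lists) were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry beside it. Both a count over all probes and a count adjusted over the list alone were made.

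The fit was tested on simulated data for restricted versus fed, over 19974 probes with 200 changed. It recovered 2 of 100 probes changed by 1 on the log2 scale and 59 of 100 changed by 2, with 3 false calls, and camera called 2 of 2 shifted lists and no other. Changes of 1 were therefore mostly missed in this simulation. In the data 2630 of 20686 probes passed, which makes the adjusted threshold less strict, so these shares need not hold there. The simulated lists were random probes that varied independently, so they do not test the preset correlation for real lists. Spots printed in duplicate correlated at 0.991 to 0.994 within an array, and no pair of arrays held identical spots. The arrays lay on 2 slides, each holding 1 group, and were scanned on 1 day, so slide and group cannot be told apart. Alternatives covered background correction, normalization, the filter on dim probes, outlier flags, the variance model, array weights, Welch's test per probe, the series matrix, replicate numbers as a block, leaving out each fish, thresholds, the probe of a list member and the list correlation. Figures were drawn with matplotlib.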

Results

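Gene expression was measured in muscle of rainbow trout (Oncorhynchus mykiss) on one-colour oligonucleotide arrays, which report the brightness of Cy3-labelled RNA bound to each spot. Control fish were offered feed to satiety 2 times per day. Restricted fish were offered feed to satiety 1 time per week, and muscle was taken after 1 month. The design text describes separate individuals in each group. Arrays of 3 fed fish, numbered 1, 3 and 4, and of 4 restricted fish, numbered 1 to 4, were analysed. A fed fish numbered 2 was not analysed here. The 75th percentile of the processed signal was 110, 210 and 137 on fed arrays 1, 3 and 4, and 162, 153, 252 and 204 on restricted arrays 1, 2, 3 and 4. Between 44.6% and 57.3% of the spots that were not controls were well above background. The number of arrays limits the precision, and the p-values measure the spread between these fish.

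The arrays were first compared with each other. Pearson correlations over 19974 probes (across probes, which are not independent replicates) were 0.942 to 0.963 within the fed group, 0.922 to 0.960 within the restricted group and 0.856 to 0.946 between groups. The leading principal component held 47.9% of the variance. Fed arrays 1, 3 and 4 scored 77.7, 30.3 and 88.9 on it, and restricted arrays 1, 2, 3 and 4 scored -57.4, -77.5, -19.2 and -42.8.

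The comparison asked which genes are expressed differently in muscle under restricted feeding. In restricted fish, probes of cathepsin B, cathepsin L, ATG4B, the growth hormone receptor, myogenin and alpha-2-macroglobulin rose, and probes of alpha-2 type I collagen, HSP47, adiponectin, myostatin 2 and phosphoglycerate dehydrogenase fell. When each fish was left out in turn, only cathepsin B of these passed in all 7 fits. The growth hormone receptor and myostatin 2 passed in 1 of 7. Cathepsin B (TC109477), a lysosomal cysteine protease, rose 4.43-fold on its brightest probe (log2 difference 2.15 ± 0.29 SE, 3 fed and 4 restricted arrays), the only 1 of its 5 probes to pass, with 2 probes above 0 and 3 below, the lowest at -0.32. Alpha-2 type I collagen (TC111031), a chain of the main fibrillar collagen, fell by 1.53 ± 0.28 on the log2 scale. Of 20686 probes tested, 2630 changed at an adjusted p under 0.05 in limma, 1385 higher and 1245 lower. A change of at least 2-fold was reached by 1184 of the higher and 1066 of the lower probes.

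The number of probes past the threshold depended on single fish. It was 203 without fed fish 1, 186 without fed fish 4, 1271 without restricted fish 1, 507 without restricted fish 2 and 1301 without restricted fish 4. Without fed fish 3 it was 3122 and without restricted fish 3 it was 2602. A set of 127 probes, 57 higher and 70 lower, passed in all 7 of these fits. Counts were lowest without fed arrays 1 and 4 and restricted array 2. These had the lowest 75th percentiles of signal (110, 137 and 153). Counts were highest without fed array 3 and restricted array 3, which had the highest (210 and 252). Whether signal strength or the fish itself set this was not tested. The groups did not overlap in 6274 probes (30.3%), where chance gives 5.71%, and in 2614 of the 2630 changed probes. Of the 84 named genes, 65 passed, 28 higher and 37 lower, counts that the rule for naming genes partly sets and that include glutamate-cysteine ligase (TC95107), which had 1 fed array. When 1 fish was left out, the number of these 65 still past the threshold was 11 without fed fish 1, 57 without fed fish 3 and 14 without fed fish 4. It was 38, 25, 56 and 44 without restricted fish 1, 2, 3 and 4. The 11 that passed in all 7 fits were cathepsin B, ATP synthase, polypyrimidine tract binding protein 2, glutamic-oxaloacetic transaminase 2, eIF2 beta, high mobility group box 1-like, liver-expressed antimicrobial peptide 2, olfactomedin-like 2B, ubiquitin specific protease 40, reproduction regulator 2 and the calpain 1 probe TC122148.

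**Figure D1:**
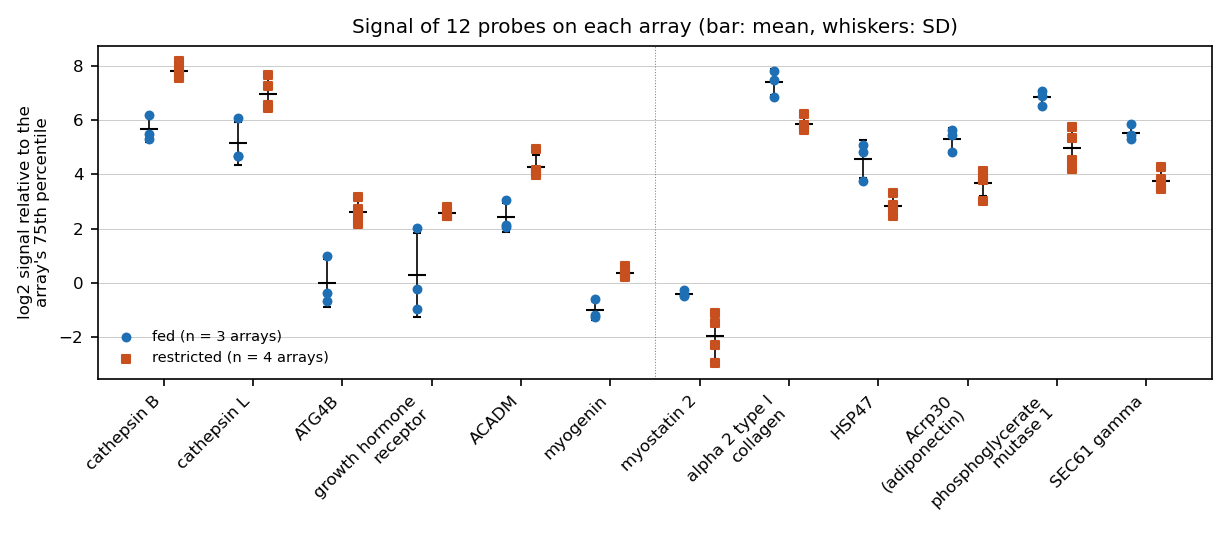
Log2 signal relative to the 75th percentile of the array (vertical axis) for 12 probes that passed the threshold, on 3 fed arrays (circles) and 4 restricted arrays (squares), with bars at the group mean and whiskers of 1 SD. The restricted means lie above the fed means for the 6 genes left of the dotted line, as for cathepsin B at 7.81 against 5.66, and below them for the 6 on the right, as for HSP47 at 2.85 against 4.56.

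The named genes with the 12 largest fitted rises included several with few fed arrays above background, so their order was not settled. Alpha-2-macroglobulin (TC102429), a plasma protease inhibitor, rose 31.2-fold (95% interval 7.65 to 127, limma adjusted p = 0.0177), with 1 of 3 fed and 4 of 4 restricted arrays well above background. A probe named ATP synthase (TC103799) was not well above background in fed fish and rose at least 13.6-fold (adjusted p = 0.00457). EGLN3 (TC102620), a prolyl hydroxylase that acts on hypoxia-inducible factor, rose by 4.18 ± 0.98 on the log2 scale, with 1 of 3 fed arrays well above background. A serum albumin 1 probe (TC132050) was not well above background in fed fish and rose at least 5.86-fold, with 3 of 4 restricted arrays well above it. Apoa4 (TC105895), an apolipoprotein of plasma lipoproteins, rose 7.88-fold and had 1 of 3 fed arrays well above background. A probe named cytochrome b (TC120094), after a gene of the mitochondrial genome, rose 7.21-fold, but of 18 probes of that name 9 lay above 0 and 9 below, and 2 rose. A probe of DNA topoisomerase I (TC104521) rose 7.55-fold, and 2 of 5 probes of that name rose. A probe of polypyrimidine tract binding protein 2 (TC120644), a splicing regulator, rose 7.70-fold, with 2 of 3 fed arrays well above background, while the other probes of that name lay below 0. Cell cycle progression 1 (TC112759) rose 8.35-fold. The other probes among the 12 largest rises carried the names phospholipase D family protein (TC113765, 8.51-fold), hydroxyproline-rich glycoprotein (TC103481, 9.70-fold) and LysR family transcriptional regulator (TC127513, 8.98-fold), each with 2 of 3 fed arrays well above background. The latter pair are plant and bacterial names given by sequence similarity, so the trout gene behind each was not settled.

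Most of the 12 largest fitted falls ended at or near background, so their order was not settled either. A probe named calpain 1 large subunit (TC122148), a calcium-dependent protease, was not well above background in restricted fish and lay at least 15.5-fold lower there (limma adjusted p = 0.00664). Ubiquitin specific protease 40 (TC96965, at least 13.3-fold lower), olfactomedin-like 2B (TC128278, at least 9.16-fold lower) and liver-expressed antimicrobial peptide 2 (TC95390, at least 8.75-fold lower) were also not well above background in restricted fish. High mobility group box 1-like (TC95784), named for a chromatin protein, fell by 3.61 ± 0.42 on the log2 scale, 12.2-fold. Reproduction regulator 2 (TC101949) fell by 3.42 ± 0.27, 10.7-fold. Mitochondrial ribosomal protein L38 (TC107107) fell by 3.51 ± 0.76 with 3 of 4 restricted arrays well above background, Samd9l (TC109773) by 3.62 ± 0.97 with 1 of 4, and a cyclic nucleotide-binding domain protein (TC122682) by 3.71 ± 0.86 with 2 of 4. Glutamate-cysteine ligase (TC95107), the enzyme of the initial step of glutathione synthesis, had a log2 difference of -3.80 ± 0.70, but was measured on 1 fed and 2 restricted arrays after outlier spots were left out. The 12 largest falls also held probes named merozoite surface protein-9 (TC123003, at least 12.5-fold lower) and cellulose synthase operon protein C (TC115983, at least 9.52-fold lower), names from a protozoan and a bacterium for which the trout gene was not settled.

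Muscle breaks down protein through lysosomes, calpains and the proteasome. Of 15 measured autophagy and lysosome genes, 3 rose, 1 fell and 11 did not pass, both over all probes and adjusted over the list alone. Cathepsin B rose as above, ATG4B (TC105943), which processes the autophagosome protein Atg8, rose 6.13-fold (log2 difference 2.62 ± 0.42, limma adjusted p = 0.0142) and cathepsin L (TC127816), another lysosomal protease, 3.56-fold (1.83 ± 0.43, adjusted p = 0.0323). Cathepsin S (TC119617), abundant in antigen-presenting cells, fell by 0.92 ± 0.22. Cathepsin D (TC120337) had a log2 difference of -0.80 ± 0.40 (adjusted p = 0.205) on its brightest probe, and 1 of its 2 probes rose. The list had a median log2 difference of 0.55 and did not pass the list test (camera adjusted p = 0.0804). Of 4 measured calpain genes, too few for the list test, 2 rose over all probes and adjusted over the list alone: calpain 1 catalytic subunit by 1.71 ± 0.30 on the log2 scale and the calpain small subunit (TC108739) by 1.38 ± 0.25. Calls were split for calpain 1, where 2 of 5 probes rose and 2 fell, TC122148 among the latter.

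None of 19 proteasome subunits passed on the brightest probe, over all probes or adjusted over the list alone (0 of 19 in limma, list camera adjusted p = 0.173), while 4 of the 48 tested probes of the list rose and 0 fell. PSMA5 (TC102346), a subunit of the proteasome core, had the smallest p, with a log2 difference of 0.88 ± 0.26 (adjusted p = 0.0546). Among 7 measured genes of the list of muscle ubiquitin ligases and ubiquitin, 1 fell and 6 did not pass, by either adjustment, on the brightest probe. The only ligase genes among them were fbxo25 and fbxo30. The others were ubiquitin (ubb), conjugating enzymes (ube2g1 and ube2d2) and ubiquitin specific proteases (usp14 and usp25). Over all 20 tested probes of that list 3 rose, from 3 genes, and 1 fell. The faller was the ubiquitin-conjugating enzyme E2 D2 (TC105719), at -1.32 ± 0.29, while 1 other probe of that name rose. The median of that list was -0.03, its mean 0.09 and its camera adjusted p 0.916. The atrophy ligases fbxo32 and trim63 were not matched to a probe and are not analysed here.

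The extracellular matrix list was lower in restricted fish with the preset correlation only. Of 23 genes measured, 5 fell over all probes and 7 fell adjusted over the list alone, none rose by either adjustment, and 18 and 16 did not pass. The list median was -0.59 (camera adjusted p = 0.00237), but adjusted p = 0.782 with an estimated correlation. HSP47 (TC128039), the collagen chaperone, was 3.27-fold lower (log2 difference -1.71 ± 0.35, limma adjusted p = 0.0231), alpha-2 type I collagen 2.89-fold lower (adjusted p = 0.0182), alpha-3 type I collagen (TC106570) 2.15-fold lower and periostin (TC120969), a matrix protein made by fibroblasts, 3.09-fold lower. The brightest alpha-1 type I collagen probe (TC107792) had a log2 difference of -0.74 ± 0.28 (adjusted p = 0.104), while all 4 probes of this gene lay below 0 and 2 fell. Beside them, 2 of 5 fat-cell markers fell over all probes and adjusted over the list alone, and 3 did not pass. Adiponectin (TC127392, named Acrp30), a hormone of fat cells in mammals, was 3.04-fold lower and G0S2 (TC104222), an inhibitor of fat-cell lipolysis, 6.48-fold lower. The fat-cell list had a median of -0.74 (camera adjusted p = 0.0359), with adjusted p = 0.782 with an estimated correlation and 0.0548 without fed fish 3. It also missed the threshold with quantile normalization (0.0726), with array weights (0.0524) and with the mean over each member's probes (0.0699).

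The list of protein folding in the endoplasmic reticulum was lower with the preset correlation only. Of 9 measured, all lay below 0, 3 fell over all probes and 4 fell adjusted over the list alone. The list median was -0.60 (camera adjusted p = 0.00807), with adjusted p = 0.782 with an estimated correlation. SEC61 gamma (TC124145), part of the channel that takes new proteins into the endoplasmic reticulum, was 3.40-fold lower (log2 difference -1.77 ± 0.27, limma adjusted p = 0.0134). GP96 (TC101478), the HSP90 of this compartment, was 2.43-fold lower, and a probe with weak similarity to calreticulin (TC112515) 2.40-fold lower. Protein disulfide isomerase A4 (TC115920) had a log2 difference of -0.97 ± 0.28 and passed adjusted over the list alone (0.0186) but not over all probes (0.0562). Beside this list, 9 of the 28 fat-cell and matrix genes fell adjusted over their own lists.

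Among 9 genes in the list of heat shock proteins and co-chaperones outside the endoplasmic reticulum, which holds the methyltransferase SmyD1b (TC118285) too, 1 rose and 3 fell over all probes, and 2 rose, 4 fell and 3 did not pass adjusted over the list alone. Hsp60 (TC121524, gene hspd1), the mitochondrial chaperonin, fell by 1.46 ± 0.24 on the log2 scale, DnaJA2 (TC123327) by 1.03 ± 0.27 and Hsp27 (TC96173, gene hspb1) by 0.89 ± 0.24, while HSP90 beta (TC118306) rose by 0.81 ± 0.21. The constitutive chaperone Hsc70 (TC110668, gene hspa8) had a difference of -0.50 ± 0.24 (limma adjusted p = 0.190). The list itself did not pass (median -0.50, camera adjusted p = 0.188).

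The list of nuclear-encoded oxidative phosphorylation genes was slightly lower with the preset correlation only. Of 33 measured, 1 rose and 5 fell over all probes, and 1 rose, 6 fell and 26 did not pass adjusted over the list alone. The median was -0.37 (camera adjusted p = 0.00807), with adjusted p = 0.782 with an estimated correlation and 0.0717 with array weights. The Rieske protein of complex III (TC122908) fell by 1.14 ± 0.21 on the log2 scale, cytochrome c oxidase subunit VIa (TC117888) by 1.03 ± 0.25 and the 9 kDa subunit of complex I (TC128953) by 0.79 ± 0.20. A probe with weak similarity to cytochrome c oxidase subunit IV (TC104898) rose by 1.11 ± 0.23. None of 12 citrate cycle genes passed in limma on the brightest probe, over all probes or adjusted over the list alone, while 1 of the 33 tested probes of the list rose (median 0.03, mean -0.01, camera adjusted p = 0.917), and succinate dehydrogenase subunit C (TC116552) had the smallest p at -0.71 ± 0.22 (adjusted p = 0.0616).

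Of 12 glycolysis genes, 1 fell and 11 did not pass, by either adjustment (median -0.40, camera adjusted p = 0.188). The brightest probe, which stood for each gene, was saturated in both groups for 2 of the 12 and in at least 1 group for 4, and the median and the list test include these. Over all 49 tested probes of the list, 12 fell, from 7 genes, and 0 rose. The gene that fell was phosphoglycerate mutase 1 (TC122700), which converts 3-phosphoglycerate to 2-phosphoglycerate, 3.67-fold lower (limma adjusted p = 0.0229). Of 5 glycogen genes, none passed over all probes and glycogen synthase (TC109687) fell adjusted over the list alone (log2 difference -0.78 ± 0.23, adjusted p = 0.0570 over all probes and 0.0429 over the list). That list had a median of -0.48 (camera adjusted p = 0.222). Of 10 genes of fatty acid use, 1 rose and 9 did not pass, by either adjustment (median -0.10, mean 0.14, camera adjusted p = 0.916). Medium-chain acyl-CoA dehydrogenase (TC99307), an enzyme of mitochondrial beta-oxidation, rose 3.66-fold (adjusted p = 0.0178), and carnitine palmitoyltransferase I (TC94736), which admits long-chain fatty acids to mitochondria, had a log2 difference of -0.56 ± 0.20 on its brightest probe and did not pass, with 2 of its 3 probes above 0, up to 1.08.

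Of 7 sterol synthesis genes, 1 rose and 6 did not pass, by either adjustment (median 0.01, camera adjusted p = 0.916). Farnesyl diphosphate synthase (TC120070), an enzyme of the mevalonate pathway, rose 2.47-fold (limma adjusted p = 0.0156). The 3 measured genes of fatty acid synthesis and storage were too few for the list test and none passed by either adjustment (median 0.33), and elovl6 (TC117101), a fatty acid elongase, had a difference of 1.02 ± 0.59 (adjusted p = 0.262). Of 10 genes of amino acid and nitrogen metabolism, 1 rose, 2 fell and 7 did not pass, by either adjustment. Phosphoglycerate dehydrogenase (TC108527), which starts serine synthesis, was 9.79-fold lower (adjusted p = 0.0134), and glutamic-oxaloacetic transaminase 2 (TC109623), the mitochondrial aspartate aminotransferase, 4.74-fold lower (adjusted p = 0.00744). The former was the only tested probe counted under its own name. It stood for the list member psat1 as the brightest of 3 probes, and the other 2 lay above 0. Spermidine/spermine acetyltransferase (TC126765, gene sat1), which starts polyamine breakdown, rose 4.09-fold. The median of this list was 0.16 and its mean -0.24 (camera direction down, adjusted p = 0.916).

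Of 5 measured myogenic regulators, 2 rose, 1 fell and 2 did not pass, by either adjustment (median 0.14, camera adjusted p = 0.601). Myogenin (TC117154), a transcription factor of muscle differentiation, rose 2.62-fold (log2 difference 1.39 ± 0.24, limma adjusted p = 0.0161). Myostatin 2 (TC99329), of the family that restrains muscle growth in mammals, was 2.96-fold lower (adjusted p = 0.0438), with 3 of 4 restricted arrays well above background. MyoD (TC105599) had a difference of 0.14 ± 0.26 (adjusted p = 0.742). In the growth hormone, IGF and insulin list, 1 of 11 genes rose and 10 did not pass, by either adjustment (median 0.29, camera adjusted p = 0.495). The growth hormone receptor (TC94971) rose 4.98-fold (limma adjusted p = 0.0412). Its mean log2 signal was 0.28 ± 1.55 (SD, n = 3) in fed and 2.60 ± 0.16 (SD, n = 4) in restricted fish. IGF-II (TC95427) had a difference of -0.37 ± 0.25 (adjusted p = 0.335).

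Among 15 fast-fibre contractile genes, 1 fell and 14 did not pass, by either adjustment (median -0.34, camera adjusted p = 0.130). Of the 15, 9 were saturated in both groups, so that no fold could be given for them. The median and the list test include these 9, so they are not read as a shift in expression. The spike-in controls saturated on most or all spots, E1A_r60_1 and E1A_r60_n9, differed by -0.36 and -0.32. The faller was a probe named alpha cardiac actin (TC131709), at -1.45 ± 0.26 (limma adjusted p = 0.0180). None of 4 measured slow-fibre genes passed in limma by either adjustment (median -0.09), and slow troponin T (TC105627) had a difference of 0.35 ± 0.49 (adjusted p = 0.654). Of 55 ribosomal proteins, 1 rose over all probes and 0 passed adjusted over the list alone in limma (median -0.02, mean 0.01, camera adjusted p = 0.916). The riser was RPS19 (TC103347), at 0.78 ± 0.19. Of the 55, 10 were saturated in both groups and 19 in at least 1, and the median, mean and list test include them. Of 32 translation factors, 1 rose and 1 fell over all probes and 1 fell adjusted over the list alone (median 0.01, camera adjusted p = 0.655). Subunit beta of eIF2 (TC95289), which brings the initiator tRNA to the ribosome, was 3.57-fold lower (limma adjusted p = 0.0107). The brightest probe of eIF4A (TC113697), an RNA helicase of initiation, rose 2.12-fold (adjusted p = 0.0381 over all probes) and missed the threshold adjusted over the list (0.0560). Of 8 eIF4A probes, 5 lay above 0 and 3 below, and only this 1 passed.

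None of 20 cell cycle and DNA replication genes passed in limma, over all probes or adjusted over the list alone (median -0.40, camera adjusted p = 0.188). Survivin (TC128252, gene birc5), a protein of dividing cells, had the smallest p at -1.39 ± 0.41 (adjusted p = 0.0555). None of 11 innate immune and interferon genes passed by either adjustment (median -0.71, camera adjusted p = 0.188), with tapasin (TC94749), which loads MHC class I, at -0.80 ± 0.31 (adjusted p = 0.117). The 4 measured circadian clock genes did not pass (median 0.13), with Period 4 (TC114098) at 0.75 ± 0.30 (adjusted p = 0.126) on the brightest probe of its list member, while 1 of the 2 probes of that member rose.

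Markers of other cell types were read beside these groups. Of 5 liver and plasma protein genes, all lay above 0, 1 rose over all probes and 2 rose adjusted over the list alone (median 0.46, camera adjusted p = 0.173). Transferrin (TC125385), the iron carrier of plasma, rose 4.24-fold (limma adjusted p = 0.0393) on its brightest probe, while another transferrin probe (TC128251) had a log2 difference of -2.63 ± 0.85 that did not pass (adjusted p = 0.0711). A further serum albumin 1 probe (TC120523) had a log2 difference of 0.78 ± 0.25 (adjusted p = 0.0698 over all probes, 0.0316 over the list), apolipoprotein B (TC127234) 0.23 ± 0.30 and the brightest alpha-1-microglobulin probe (TC114737) 0.07 ± 0.23. Another of the 4 alpha-1-microglobulin probes (TC127394), not well above background in fed fish, rose at least 2.77-fold (adjusted p = 0.0416), and over all 15 tested probes of the list 4 rose, from 3 genes, and 0 fell. Alpha-2-macroglobulin, albumin TC132050 and Apoa4, the plasma proteins among the largest rises, moved with them. Of 9 white blood cell markers, 2 fell and 7 did not pass, by either adjustment (median -0.37, camera adjusted p = 0.176). The MHC class II invariant chain (TC101937, gene cd74) fell by 0.84 ± 0.23 and Rac2 (TC111838), a GTPase of blood cells, by 1.07 ± 0.28. None of 6 red cell markers passed in limma by either adjustment (median 0.06, mean 0.07, camera direction down, adjusted p = 0.916), with alpha globin (TC118397) at 0.16 ± 0.29 and transferrin receptor 1a (TC101346) at -0.60 ± 0.24. None of 8 skin markers passed (median -0.37, camera adjusted p = 0.514), with desmoplakin (TC129803) at -0.68 ± 0.30. None of 4 vessel and nerve markers passed (median -0.41), with myelin proteolipid protein (TC103133) at -0.85 ± 0.30 (adjusted p = 0.0897).

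**Figure D2:**
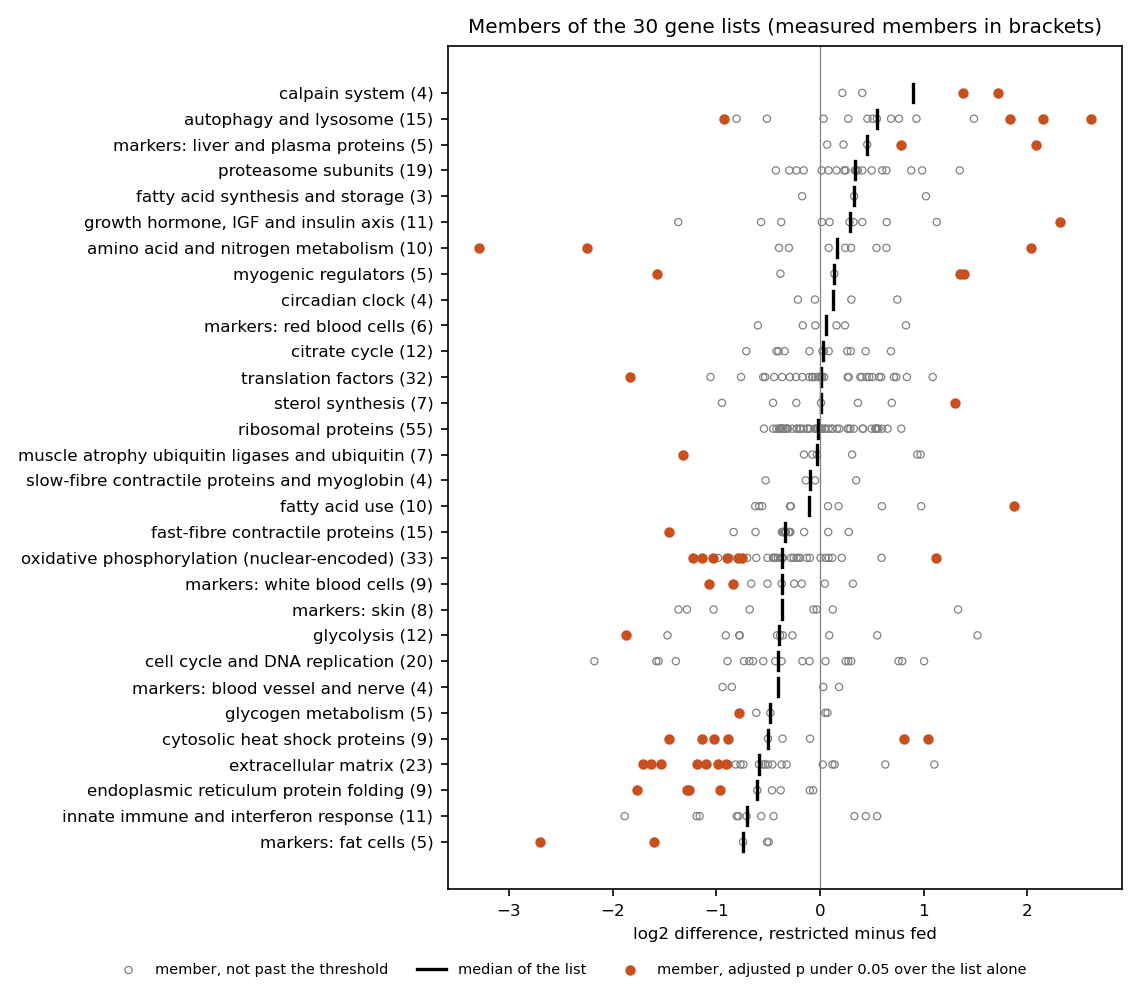
Log2 difference, restricted minus fed (horizontal axis), of every measured member of the 30 gene lists (vertical axis, number of measured members in brackets), with filled points for members past an adjusted p of 0.05 over the list alone and bars at list medians. The list medians run from -0.74 for fat-cell markers to 0.89 for the calpain system. Members saturated in both groups (9 fast-fibre, 10 ribosomal, 2 glycolysis and 1 translation factor) are drawn without a mark and enter the medians, though their differences are not settled.

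Each gene of a list was represented by its brightest probe, and counts over all tested probes of a list could differ from counts of genes. Among 40 autophagy and lysosome probes 6 rose and 1 fell, among 18 growth hormone, IGF and insulin probes 3 rose and 0 fell, and among 148 ribosomal protein probes 5 rose and 0 fell. Among 56 extracellular matrix probes 0 rose and 11 fell, among 30 endoplasmic reticulum folding probes 0 and 8, among 11 fat-cell probes 0 and 3, and among 6 probes of fatty acid synthesis and storage 0 and 1. Both directions were found among 65 oxidative phosphorylation probes (2 rose, 8 fell), 28 probes of the heat shock list (1 and 9), 45 white blood cell probes (1 and 5) and 59 innate immune probes (1 and 3). The same held for 97 translation factor probes (3 and 4), 97 fast-fibre probes (2 and 3), 24 amino acid and nitrogen probes (3 and 4) and 23 probes of fatty acid use (1 and 2). Of 28 skin probes 1 fell, and of 39 cell cycle and 23 red cell probes 0 passed in limma.

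In all, 4 of 25 lists tested passed with the preset correlation, all lower (extracellular matrix, oxidative phosphorylation, endoplasmic reticulum folding and fat-cell markers). With an estimated correlation 0 of 25 passed in camera, 0 at an unadjusted p under 0.05, and fry, which tests each list without reference to other genes, called 1, the liver and plasma list (higher, adjusted p = 0.0122). The mixed form of fry, which counts changes in either direction, called 18 of 25. Of the 35 ways to split the 7 arrays into 3 and 4, 18 gave 4 or more lists. The fed and restricted arrays lay on different slides, so slide and feeding could not be separated.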

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

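The tests on fat and connective tissue, on liver or blood, and on spike-in controls outside the linear range were chosen after the results they bear on had been seen. The tests on splits of the arrays, linear spike-in controls and slides were chosen before, but the limit of the spike-in test to probes of like brightness was set after its result was seen.

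Among 85 sets of 4 restricted values, 6 had a value set apart from the others by a gap that chance gives in about 1 of 20 sets (Dixon's ratio of gap to range), so the number lies near what chance gives. Slow troponin T was 1.73 on the log2 scale in restricted fish 4, against 0.43 to 0.63 in the other restricted fish. PSMA5 was 6.45 in restricted fish 1, against 5.68 to 5.80. The Rieske protein of complex III was 1.63 in restricted fish 2, against 1.94 to 1.97. Ubiquitin specific protease 40 was -3.59 in restricted fish 4, against -4.79 to -4.60, and liver-expressed antimicrobial peptide 2 was -3.59 there too, against -4.79 to -4.59. Olfactomedin-like 2B was -5.63 in restricted fish 3, against -5.07 to -4.96. The last 3 of these probes were not well above background in restricted fish.

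The count of 2630 changed probes was weighed against chance, brightness of the scans and slide. Of the 35 splits of the 7 arrays into 3 and 4, 1 gave as many, the real one, and the highest other gave 2. No result can be rarer than 1 of 35 here, so chance is unlikely for this count but not excluded. The 4 spike-in controls in the linear range differed between the groups by 0.15, 0.17, 0.21 and 0.27 on the log2 scale, a range of 0.115, which argues against a brightness-dependent difference between the scans for the 667 changed probes with both means within their brightness (0.82 to 6.03). For the other 1963 it stays open, since the 6 dim or saturated spike-ins differed by -0.65 to 0.27, a range of 0.919 that decides nothing. All 4 linear spike-ins lay higher in restricted fish, by 0.15 to 0.27. Scaling to them would move each difference between the groups down by about that much. No fit with that scaling was run. The number of slides holding arrays of both groups was 0, so a difference between slides cannot be told apart from feeding, and a response of the muscle to feeding stays open as the biological hypothesis.

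The lower collagen, endoplasmic reticulum folding and fat-cell genes may reflect lower expression under restricted feeding or less fat and connective tissue in the muscle sampled. Of the 28 measured members of the fat-cell and extracellular matrix lists, 23 lay below 0, 9 fell over their lists and 0 rose, where at least 3 rising would have argued against less of that tissue. With 0 rising this count cannot decide, since lower expression of these genes would give the same. Genes of the endoplasmic reticulum folding list did not enter it. All 5 fat-cell markers and 21 of 23 matrix genes were well above background on every fed array, and none of them stood in another list, so both explanations stay open. Which trout cells express these markers was not tested. The number of lists gives no further weight, since 18 of the 35 splits of the arrays gave at least 4 lists, the highest other 7, and chance cannot be excluded for that count.

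The higher plasma-protein genes (alpha-2-macroglobulin, albumin, transferrin and Apoa4) may reflect expression in muscle under restricted feeding or liver tissue or blood left in the muscle sampled. Of 5 liver and plasma list members, all above 0, 2 rose over the list. Apolipoprotein B and alpha-1-microglobulin differed by 0.23 and 0.07 on their brightest probes, under the 0.25 that had been set as arguing against carried-over tissue, but their 95% intervals reached 0.90 and 0.60, and another alpha-1-microglobulin probe (TC127394) rose at least 2.77-fold, so, with the intervals taken into account after the values were seen, 0 members stayed within it by more than their spread. Transferrin TC125385 went from a mean of 1.06 to 3.14 and TC128251 from -1.31 to -3.94, albumin TC120523 from -0.64 to 0.14 and apolipoprotein B from 4.05 to 4.28, and all 5 members were already well above background in every fed fish. The arrays read RNA, so plasma proteins carried in blood would not be read. Red cell markers gave no sign of more blood, but 1 of the 6 was saturated in 1 group, so its difference was not settled. Alpha globin differed by 0.16 ± 0.29, and of 23 red cell probes 12 lay above 0, 11 below and 0 passed in limma. These values do not exclude RNA of blood cells. Expression in muscle and carried-over liver tissue also stay open.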

How the results depend on the processing

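Centring on bins of probe base composition was chosen after the data were seen, and the other alternatives before. No named gene or list past the threshold reversed direction under any setting run. The count of 2630 probes was 1353 of 37231 with no filter on dim probes (643 higher, 710 lower, median of all probes -0.20 on the log2 scale), 5071 with array weights, 4952 at an adjusted p under 0.1 and 606 of 5856 with the probes of one name averaged. Welch's test per probe gave 0 probes (4925 at an unadjusted p under 0.05, smallest adjusted p 0.0506), although 2628 of the 2628 probes it shared with limma's calls kept their direction. On the simulated data Welch's test also called 0 probes, though 200 were changed, so its 0 here cannot speak against the calls. Leaving out 1 fish gave 186 to 3122 probes. Nothing in the labels says that the numbers pair the fish. Deviations of same-numbered arrays correlated at 0.01, -0.01 and 0.06, and 0 of 3 fed arrays correlated best with their own number. So few arrays cannot exclude a pairing. With the replicate block 0 probes passed in limma (5097 unadjusted, smallest adjusted p 0.0590). The slide as a block was not run, since each slide held 1 group. Other settings gave 2250 to 3482 probes, base composition centring 2698, of which 2469 were among the 2630. The 4 lists were 7 with normexp background (3 higher, 4 lower), 0 with an estimated correlation (0 unadjusted) and 4 to 6 when 1 fish was left out, and 3 to 6 otherwise. Of 1274 refits of the 65 named genes past the threshold, 897 passed and 377 did not, including all 64 with Welch's test and all 64 with the replicate block. Of 87 refits of the 4 lists, 78 passed. Of 377 refits of named genes that had not passed, 30 passed. The cause was not tested, beyond fewer fish or fewer degrees of freedom in some fits. Signal over background limits 151 changed probes in fed and 43 in restricted fish to bounds.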

Other observations

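The values in this part were chosen after the results had been seen, and no further test was run on them.

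Several gene names were carried by more than 1 probe past the threshold in the same direction. GAPDH, the glycolytic dehydrogenase, had 8 probes under the name glyceraldehyde-3-phosphate dehydrogenase, all below 0, and 5 fell, with log2 differences from -2.89 to -0.93. All 5 probes of alpha-2-macroglobulin rose, by 1.82 to 4.96. Cu/Zn superoxide dismutase, an antioxidant enzyme, had 3 of 4 probes that fell (-1.04 to -0.86), macrophage migration inhibitory factor 3 of 3 (-1.26 to -1.16), histidyl-tRNA synthetase 3 of 3 (-1.44 to -1.37) and the collagen chaperone HSP47 3 of 3 (-2.45 to -1.71). The splicing factor SRSF3, under the name arginine/serine-rich 3, had 3 of 4 that fell, the GTPase CDC42 3 of 5 and mitochondrial ribosomal protein L17 3 of 7. Proteasome subunit alpha type 7 had 3 of 7 probes that rose (0.97 to 1.48), whereas the brightest probes of the 19 listed proteasome subunits did not pass. The calpain regulatory subunit had 4 of 8 that rose (1.06 to 1.46), and flightless-I, an actin-binding protein, and upstream transcription factor 1 had 3 of 4 each. Glutathione S-transferase, a family that conjugates glutathione, had 7 probes that rose and 12 that fell among 76, and gelsolin 3 and 3 among 31. Probes of one name can read the same gene or duplicated copies, so they are not independent.

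By their product names, 103 probes under 23 names stood for genes of the mitochondrial genome. Of these, 9 rose, 3 fell and the median log2 difference was 0.05. Whether each reads that genome was not settled. Fed means of the cytochrome b probes ran from -2.45 (TC127568) to 8.85 (TC130394). The brightest of them, TC130394, had a log2 difference of -0.38 ± 0.29 and did not pass. NADH dehydrogenase subunit 4 had 4 of 7 probes that rose (0.91 to 1.83). Over all names with at least 2 changed probes, 82 of 93 had changes in 1 direction and 11 in both.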
